A study of Dugesia japonica with 4 samples.

How the data were processed

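Single-cell ATAC-seq was measured in 4 libraries of the planarian Dugesia japonica, 2 of intact heads and 2 of head blastema, grouped by the sample titles. Per the labels' protocols, tissue was chopped and lysed, nuclei were filtered, counted and loaded on a 10x Genomics controller, and libraries were sequenced as paired-end reads on an Illumina NovaSeq instrument. The submitters' processing notes name Cell Ranger ATAC and Signac, and the version of the first, 2.1.0, is given per the file headers. The reference is a planarian assembly in scaffolds with an annotation, and its name and version are not given in the sources used here. No step recorded in the labels says how the authors used Signac.

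The fragment files deposited by the authors list, per the file headers and values, 1 fragment per line with its scaffold, start, end, barcode and the count of read pairs that showed it, duplicates included. Whether fragment ends were shifted for the transposase is not given in the sources used here, and they were used as deposited. The filtered matrices deposited by the authors hold raw counts per peak and barcode, most often 2 per entry, which is read here as cut ends, for the barcodes kept as cells, with peaks called in each library separately, so peaks of different libraries are not the same features. The barcodes were kept as called by the authors, with no further filter. In the matrices, the median count of ends per nucleus was 2929 and 1867 in the intact head replicates 1 and 2 and 1853 and 2390 in the blastema replicates 1 and 2. These values correlated with the ends counted here in the union regions at 0.997 to 0.999 across nuclei.

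To compare libraries, the 4 peak lists were merged where peaks overlapped or touched, which gave 127005 regions on 2516 scaffolds covering 115.5 Mb. A fragment of a called nucleus counted once in each region that held at least 1 of its ends. Totals in regions ranged from 8851827 to 15393419 per library. Duplicate read pairs were not counted, and intervals cover counting error and the spread between libraries, not bias of the transposase. Coordinates are those of the authors' build, counted from 1.

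Fragments were summed per library, since nuclei are not replicates, and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust quasi-likelihood fit, group as the only term). Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, and the standard error of a log2 fold change is its size divided by the square root of the F statistic. The biological coefficient of variation was 9.42%. Log2 values per library used a prior count of 1. DESeq2 1.42.0 and limma 3.58.1 were installed beside it, and DESeq2 served for alternatives.

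Nuclei were clustered with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2. The 76827 regions open in at least 0.5% of nuclei entered a term frequency and inverse document frequency transform and a singular value decomposition with 30 components. The component that correlated with depth at over 0.5 (r = 0.94) was left out, which kept 29. A graph of 20 neighbours was divided by the Leiden method at a resolution of 0.5, and at a resolution of 1 for sub-clusters. Libraries were not aligned. Doublets were scored against simulated doublets at an assumed rate of 0.8% per 1000 nuclei, which marked 1591 nuclei (5.74%). They stayed in the main results and were left out as an alternative. Shares of nuclei were tested with edgeR on the number of nuclei per cluster, with all nuclei of the library as its size. Within clusters, fragments were summed per library and cluster and tested as above, for clusters with at least 50 nuclei in each library. Clusters 15 and 21 had fewer and were not fitted. Peak overlap was computed with bedtools 2.31.1, with a minimum of 1 bp.

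Regions named in the text follow a rule fixed before the data were examined: among regions past the threshold, with a mean log2 CPM at or above the median of those tested and both blastema libraries on the same side of both intact libraries, the 12 with the largest change in each direction, and the 3 largest in each direction within each cluster. The text names part of these. Regions picked otherwise are said to be.

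The scripts were tested on simulated data with 200 regions changed by known folds, for the real means and library sizes. Over 125651 regions of the whole libraries, 57% of 2-fold and 99% of 4-fold changes were recovered, with 10 unchanged regions called. Within cluster 1 (26247 regions) these shares were 28.4% and 87%, with 1 unchanged region called, and within cluster 11 (10429 regions) 41.5% and 91%, with 5. Within cluster 14 (7596 regions), which has fewer nuclei, they were 29.7% and 83.8%, with 8 unchanged regions called. These 8 came beside 27 and 83 recovered changes, so they give no number of false calls for the 6 regions called in the data. In the test of differences between clusters (25003 regions), with regions changed in cluster 1 alone and an assumed spread, they were 0% and 27.8%, with 1. In the whole libraries, clusters 1 and 11 and the test of differences, far more regions were called in the data than were changed here. This loosens the adjusted threshold in the data, so the shares recovered are not those of the data. In 50 simulated tables of 21 shares, 66% of 2-fold and 96% of 4-fold changes were recovered, and 16 unchanged clusters were called over all tables.

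Alternatives were other scaling factors, the DESeq2 test, no filter, regions with peaks in at least 2 libraries, fragments under 120 bp, cut ends, equal numbers of nuclei, a replicate block, each library left out in turn, other cluster settings and other overlap limits. Thinning to equal depth and leaving out doublets in the tests of regions were added after seeing the data. So were clusters with at least 200 nuclei in each library and clusters built without the regions that had changed within any cluster. Tests planned for genes, gene lists, cell type markers, motifs and GC content needed a genome with its annotation, which was not used here.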

Results

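Chromatin accessibility was measured in single nuclei of the planarian Dugesia japonica, a freshwater flatworm that regrows a lost head, by droplet-based single-cell ATAC-seq, in which a transposase cuts and tags open DNA. Nuclei came from intact heads (2 libraries) and from head blastema, the new tissue that forms at the wound after amputation (2 libraries). The titles of all 4 libraries carry the mark of 5 days post amputation, and the series design describes intact animals and animals at that time. What the mark means for the intact heads is not stated. Nuclei were loaded with a target of 7000 per library.

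The deposited barcodes held 7548 and 6527 nuclei in the intact head replicates 1 and 2, and 7179 and 6480 nuclei in the blastema replicates 1 and 2. These nuclei held 23977495, 14511888, 14017012 and 16043653 fragments, in the same order. The median number of fragments per nucleus was 2653.5 and 1790 in intact heads, against 1758 and 2267.5 in blastema, so depth differed more between replicates than between groups. Of these fragments, 63.7% and 62.1% lay in the union of the peak lists in intact heads, and 62.9% and 62.7% in blastema. Fragments under 120 bp made up 36.1% and 33.5% in intact heads and 38.4% and 36.5% in blastema. A fragment was seen in 3.56 read pairs on average in the intact head replicate 1 and in 5.69 to 6.26 in the other libraries. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these 4 libraries, which may be technical.

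The 4 peak lists held 91388 and 77443 peaks in intact heads and 85788 and 86990 peaks in blastema, called in each library on its own. On average 78.1% ± 5.26 (SD, n = 4 ordered pairs) of the peaks of a list overlapped a peak of the other replicate of its group, and 73.4% ± 3.51 (SD, n = 8 ordered pairs) overlapped a peak of a library of the other group. The ranges of the 2 kinds of pair overlapped, at 71.7% to 84.6% and 68.6% to 78.0%, and this comparison carried no test. Merged, the lists gave 127005 regions with a median length of 912 bp, of which 50176 were covered by a peak in all 4 libraries.

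Open chromatin differed between blastema and intact head in 26242 of 125948 tested regions. In blastema 14221 regions were higher, with a median log2 fold change of 0.91, and 12021 were lower, with a median of -0.80. The order of these counts turned with all fragments as library size (12798 higher and 13601 lower) and with fragments under 120 bp (7370 and 9007). Large gains were more frequent than large losses: 5831 regions rose and 2876 fell by at least 2-fold, and 270 rose and 20 fell by at least 4-fold. The gene content of the regions was not analysed here, so regions are named by scaffold, start and end in the authors' unnamed planarian build.

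Among the 12 most increased of the well-covered regions, scaffold31:949461-950344 rose by a log2 fold change of 3.11 (SE 0.20), from 1.29 and 1.91 log2 CPM (counts scaled to library size) in intact heads to 4.61 and 4.69 in blastema. Scaffold420:296699-297480 rose by 3.05 (SE 0.23), scaffold589:94624-95555 by 3.04 (SE 0.21) and scaffold1240:108894-109826 by 2.94 (SE 0.23). By the mean CPM of the 4 libraries, each weighted equally, these 4 regions were most open in nuclei of clusters 10, 2, 1 and 2, described below. Cluster 15 came next for scaffold420:296699-297480, at 20.4 CPM against 22.1. In blastema alone the first clusters were the same, at 58.6, 40.5, 49.4 and 34.8 CPM, whereas in intact heads alone they were clusters 10, 7, 20 and 21, on 7, 11, 4 and 3 fragments. Scaffold188:216970-217996, which rose by 2.92 (SE 0.24), was most open in cluster 11 in both groups. The edgeR adjusted p of these 5 regions ranged from 1.63e-20 to 6.97e-16. Both blastema libraries lay above both intact libraries in each, which the rule for naming regions required.

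Among the 12 most decreased regions, scaffold528:200737-201597 had a log2 fold change of -2.54 (SE 0.27) and scaffold889:274220-275194 one of -2.32 (SE 0.22), and both were most open in cluster 15, at 50.5 and 129 CPM against medians over clusters of 1.29 and 1.72. Cluster 11 came next for scaffold889:274220-275194, at 34.7 CPM. Scaffold2378:5088-5868 (-2.05, SE 0.24), scaffold1367:325538-326460 (-2.02, SE 0.24) and scaffold728:153493-154384 (-1.88, SE 0.18) were most open in cluster 16. Scaffold632:109652-110612 (-1.91, SE 0.29) was most open in cluster 6 and scaffold448:276328-277213 (-1.86, SE 0.29) in cluster 19. Ranked in either group alone, the first clusters were the same, except that in blastema scaffold2378:5088-5868 was most open in cluster 15, on 8 fragments. The rank in blastema of scaffold632:109652-110612 and of scaffold448:276328-277213 rested on 4 fragments each. The edgeR adjusted p of these 7 regions ranged from 8.78e-13 to 7.63e-07.

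**Figure D1:**
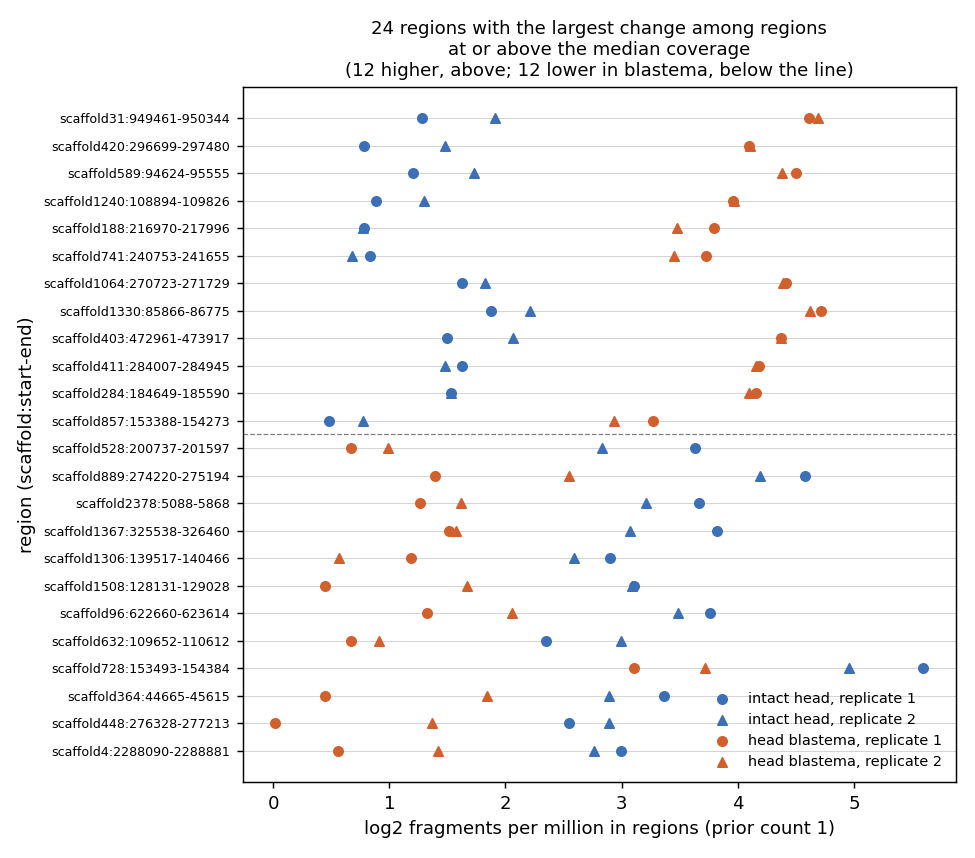
Log2 CPM in regions (x axis) of the 24 regions with the largest change among those at or above the median coverage, 12 higher and 12 lower in blastema (y axis, scaffold and position), 1 point per library, with circles for replicate 1 and triangles for replicate 2. In scaffold31:949461-950344 the blastema libraries lie at 4.61 and 4.69 and the intact libraries at 1.29 and 1.91.

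The test was edgeR's quasi-likelihood test on fragments summed per library. Across regions, log2 values correlated at 0.95 within each group and at 0.86 to 0.89 between groups, and regions are not independent replicates. The count fell to 8276 with the Wald test of DESeq2, to 16377 with fragments under 120 bp, to 11838 without blastema replicate 1 and to 15673 without blastema replicate 2.

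The nuclei of all 4 libraries fell into 21 clusters, numbered by size and left unnamed because no gene annotation was used. Blastema held more nuclei of clusters 1, 2, 10, 11 and 12. Cluster 1 made up 10.4% ± 0.27 (SD, n = 2) of intact head nuclei and 19.2% ± 1.55 of blastema nuclei, a 1.85-fold higher share (adjusted p = 0.00207, edgeR). Cluster 2 went from 5.52% ± 0.95 to 12.6% ± 1.97, 2.28-fold (adjusted p = 0.000111, edgeR), and cluster 11 from 2.51% ± 0.41 to 5.48% ± 0.61, 2.18-fold (adjusted p = 0.000322, edgeR). Clusters 12 and 10 were 1.69-fold and 1.63-fold higher (adjusted p = 0.00937 and 0.0141, edgeR).

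Intact heads held more nuclei of clusters 3, 6, 9, 14, 16, 18, 19 and 21. Cluster 6 made up 8.95% ± 1.40 (SD, n = 2) of intact head nuclei against 4.40% ± 0.17 of blastema nuclei, 2.03-fold. Cluster 16 made up 3.89% ± 0.72 against 1.36% ± 0.17, 2.86-fold. Clusters 18, 19 and 21 were 2.79-fold, 3.39-fold and 3.79-fold more frequent in intact heads, and cluster 14 was 2.19-fold more frequent. The edgeR adjusted p of these 6 clusters ranged from 4.85e-06 to 0.000581. Clusters 3 and 9 were 1.74-fold and 1.76-fold more frequent (adjusted p = 0.00765 and 0.00642, edgeR). Cluster 15 made up 5.34% and 3.63% of the intact libraries and 0.40% and 1.27% of the blastema libraries, but missed the threshold (adjusted p = 0.0758, edgeR). It also missed it without intact head replicate 1 (adjusted p = 0.315, edgeR) and without intact head replicate 2 (0.273). At a resolution of 1, tested over 21 clusters, it missed it as well (adjusted p = 0.0892, edgeR). In the test of the sub-clusters themselves, sub-cluster 17, with 751 of its 755 nuclei in cluster 15, passed (adjusted p = 0.0106, edgeR). Cluster 15 passed without blastema replicate 1 (adjusted p = 0.0128, edgeR), without blastema replicate 2 (2.75e-05) and without doublets (2.80e-08), which made up 19.3% of its nuclei. It also passed among nuclei with at least 2000 fragments (0.00177) and with components centred per library (0.0226). Clusters 4, 5, 7, 8, 13, 17 and 20 differed by at most 1.36-fold in either direction and missed it as well. Cluster 8 passed among nuclei with at least 2000 fragments (adjusted p = 0.0267). With components centred per library, cluster 5 passed with a log2 ratio of -3.69 (SE 0.31, adjusted p = 9.29e-13, edgeR) against -0.39 (SE 0.25), and cluster 11 had one of 2.93 (SE 0.29) against 1.12 (SE 0.26).

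**Figure D2:**
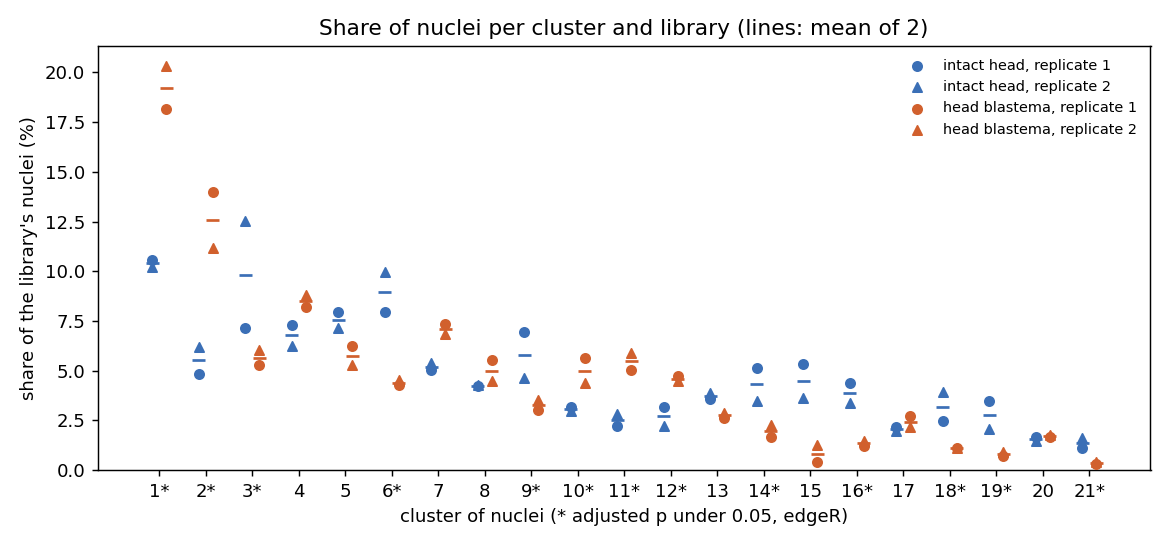
Share of each library's nuclei (y axis, %) in each of 21 clusters (x axis), 1 point per library and a line for each mean of 2, with circles for replicate 1, triangles for replicate 2 and a star at each cluster past an adjusted p of 0.05. Cluster 1 lies at 10.2% and 10.6% in intact heads and at 18.1% and 20.3% in blastema.

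Shares sum to 100% within a library, so a gain in some clusters lowers others. The clusters were also built without the 8719 of the 76827 clustering regions that had changed within any cluster, since those could sort nuclei by group. There, clusters 1 and 2 formed 1 cluster with 16.0% ± 0.59 (SD, n = 2) of intact and 31.3% ± 0.47 of blastema nuclei (adjusted p = 0.00865, edgeR). Clusters 11, 12 and 17 formed another, with 6.85% ± 0.48 and 12.4% ± 0.18 (adjusted p = 0.00865, edgeR). Clusters 6, 16, 18, 19 and 21 stayed lower in blastema by 2.04-fold to 3.43-fold, clusters 15 (5.20-fold lower) and 7 (1.38-fold higher) then passed (adjusted p = 0.0158 and 0.0418, edgeR), and cluster 3 missed the threshold (adjusted p = 0.0891, edgeR). Among nuclei with at least 2000 fragments, clusters 3, 9 and 21 missed it (adjusted p = 0.0528, 0.0528 and 0.0980), with log2 ratios of -0.67 (SE 0.28), -1.22 (SE 0.44) and -3.08 (SE 1.15) against -0.80, -0.81 and -1.92 with all nuclei. Cluster 1 had a ratio of 1.71 (SE 0.25) there against 0.89, and cluster 2 could not be matched there. With components centred per library, clusters 2 and 14 could not be matched and cluster 21 missed it (-0.25, SE 0.30, adjusted p = 0.469). Leaving out 1 library kept the call of clusters 2, 11, 16, 18, 19 and 21 each time. Cluster 1 missed it without blastema replicate 2 (adjusted p = 0.0759), clusters 6 and 14 without blastema replicate 1 (0.0632 and 0.0853), and clusters 3, 9, 10 and 12 without either blastema replicate (0.0708 to 0.302). Without intact head replicate 1, cluster 9 also missed it (adjusted p = 0.154), as did clusters 3, 10 and 12 without intact head replicate 2 (0.273, 0.0638 and 0.145).

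A finer division of the same nuclei gave 31 sub-clusters, which were not nested in the clusters, so their shares include nuclei of other clusters. Sub-clusters 1 and 6, with 99.4% and 98.5% of their nuclei in cluster 1, went in opposite directions. Sub-cluster 1 went from 3.69% ± 1.32 (SD, n = 2) of intact nuclei to 17.4% ± 0.76 of blastema nuclei, 4.72-fold higher, whereas sub-cluster 6 went from 6.76% ± 1.70 to 1.47% ± 0.69, 4.60-fold lower (adjusted p = 0.00268 and 0.00541, edgeR). Sub-cluster 12, with 89.2% of its nuclei in cluster 11 and 10.2% in cluster 5, went from 1.34% ± 0.40 to 5.83% ± 0.29, 4.35-fold higher, and sub-cluster 31, which lay in cluster 11, from 1.25% ± 0.07 to 0.31% ± 0.19, 4.01-fold lower (adjusted p = 0.00268 and 0.00869, edgeR). In cluster 5, sub-cluster 4 was 1.68-fold lower in blastema (adjusted p = 0.0468, edgeR), while sub-cluster 27 missed the threshold (adjusted p = 0.176, edgeR). The sub-clusters were found with the regions that changed among their features.

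**Figure D3:**
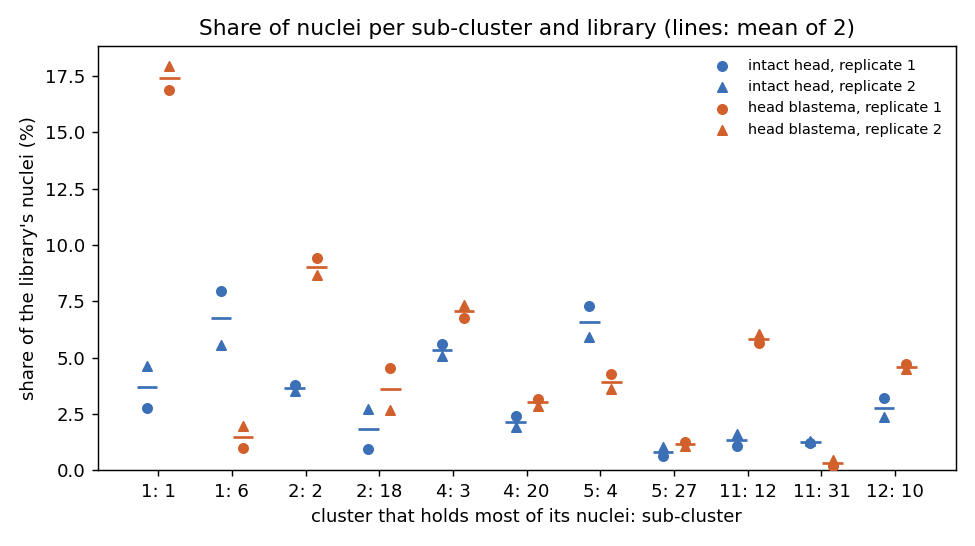
Share of each library's nuclei (y axis, %) in the sub-clusters with most of their nuclei in clusters 1, 2, 4, 5, 11 or 12 (x axis, that cluster and the sub-cluster), 1 point per library and a line for each mean of 2, with circles for replicate 1 and triangles for replicate 2. The means of sub-clusters 1 and 6 are 3.69% and 6.76% in intact heads and 17.4% and 1.47% in blastema.

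Open chromatin also differed within clusters. Among the 19 clusters with at least 50 nuclei in each library, 13246 differences were called, 8322 higher and 4924 lower in blastema, in 9114 distinct regions. Cluster 1 held 5229 of them (2992 higher and 2237 lower), cluster 5 held 1691, cluster 4 held 1584, cluster 12 held 1453, cluster 11 held 1447 and cluster 2 held 775. Gains outnumbered losses in each of these except cluster 11, with 713 higher and 734 lower, and that order turned when 1 library was left out: in cluster 1 without intact head replicate 2 (2118 higher, 2357 lower), in cluster 5 without intact head replicate 1 (344 and 360) or 2 (914 and 1338), and in cluster 11 without intact head replicate 1 (347 and 279), intact head replicate 2 (791 and 565), blastema replicate 1 (346 and 224) or blastema replicate 2 (476 and 313). Of the 9114 regions, 4780 were also called in the whole libraries. In clusters 1, 5 and 11 the groups were spread differently over sub-clusters. Of the nuclei of cluster 5, sub-cluster 4 held 91.5% and 82.6% in intact heads against 68.5% and 68.1% in blastema. Sub-cluster 12 held 0.66% and 1.72% of them against 11.2% and 11.1%, and sub-cluster 27 held 7.64% and 14.2% against 20.4% and 20.5%. Of the nuclei of cluster 1, sub-cluster 6 held 73.8% and 53.9% in intact heads against 5.45% and 9.49% in blastema, and sub-cluster 1 held 26% and 45.2% against 92.2% and 87.9%. Of the nuclei of cluster 11, sub-cluster 31 held 54.2% and 46.4% against 3.59% and 7.57%, and sub-cluster 12 held 45.2% and 53% against 96.4% and 92.2%.

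In cluster 1, scaffold420:296699-297480 held 2 and 0 fragments in the intact libraries and 39 and 53 in the blastema libraries, too few in intact heads for a fold change, while scaffold616:161445-162331 had a log2 fold change of -2.77 (SE 0.30). In cluster 4, scaffold1216:102307-103191 rose by 3.59 (SE 0.39), with only 5 and 3 fragments in intact heads. There, scaffold976:125080-126018 had a log2 fold change of -2.95 (SE 0.46), with only 3 and 4 fragments in blastema. In cluster 5, scaffold349:65235-66141 rose by 2.57 (SE 0.25) and scaffold143:786974-788649 by 2.75 (SE 0.33). In cluster 11, scaffold143:784463-785533, on the same scaffold, rose by 3.75 (SE 0.48), with only 4 and 3 fragments in intact heads. There, scaffold889:274220-275194 had a log2 fold change of -3.26 (SE 0.41), with only 4 and 5 fragments in blastema. In cluster 12, scaffold236:294064-294976 held 3 and 0 fragments in intact heads against 36 and 37 in blastema, and scaffold58:985562-986471 had a log2 fold change of -1.88 (SE 0.25). The edgeR adjusted p of these 10 regions ranged from 3.47e-08 to 0.000411. Both regions of cluster 12 missed the threshold without intact head replicate 1 (adjusted p = 0.378, edgeR) and without intact head replicate 2 (0.137).

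Across clusters, 2526 regions were called in at least 2 clusters, of which 1610 were higher in each call, 537 lower in each call and 379 mixed. Of 35 regions called in at least 7 clusters, 33 were higher in each call and none was lower in each call. Scaffold167:232368-233311 was higher in 12 of the 18 clusters in which it was tested, by log2 fold changes of 1.34 to 2.49, and scaffold188:1366932-1367840 in 11 of 17. In the whole libraries they rose by 1.64 (SE 0.14) and 1.34 (SE 0.13). These 2 regions were picked after their values were seen.

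**Figure D4:**
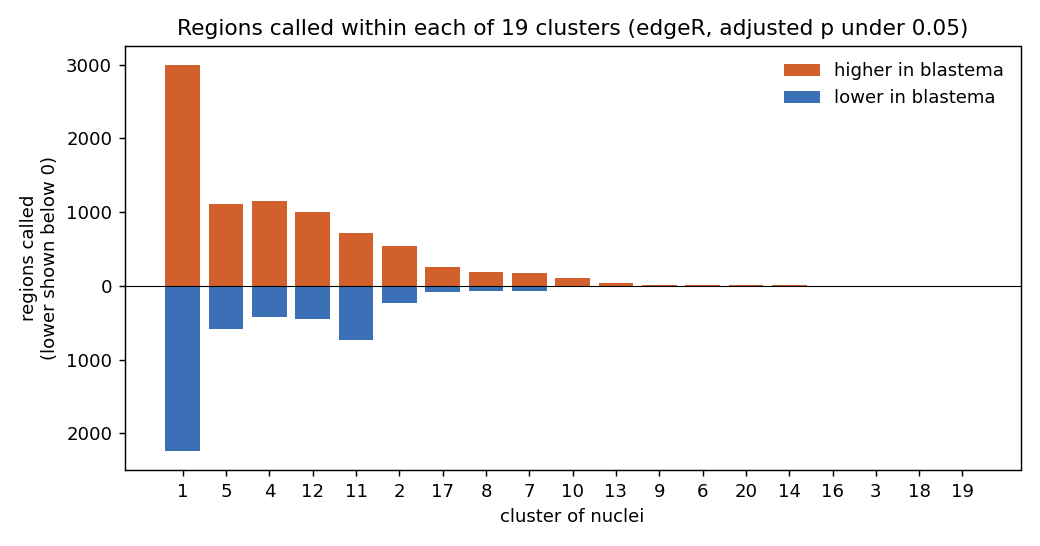
Regions called within each of 19 clusters (x axis, ordered by their number), with bars above 0 for regions higher and bars below 0 for regions lower in blastema (y axis, number of regions). Cluster 1 holds 2992 higher and 2237 lower regions.

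Clusters 3, 18 and 19 held 0 calls by edgeR, with either set of scaling factors, and 1089, 228 and 215 regions at an unadjusted p under 0.05. DESeq2's own test was not run within clusters. Without doublets, clusters 18 and 19 held 2 and 13 calls. Without intact head replicate 2, clusters 3, 18 and 19 held 235, 13 and 22 calls, and without intact head replicate 1 clusters 3 and 18 held 32 and 5. Counts depended on single libraries and on the number of nuclei. With equal numbers of nuclei per library the total was 7589, without intact head replicate 1 it was 5167, without blastema replicate 1 it was 4242 and without blastema replicate 2 it was 4989. In the order of clusters 1, 5, 4, 12, 11 and 2, the counts were 2590, 704, 563, 0, 626 and 240 without intact head replicate 1, 1979, 276, 688, 203, 570 and 218 without blastema replicate 1, and 1893, 440, 719, 391, 789 and 348 without blastema replicate 2. Without intact head replicate 2, cluster 12 held 0 and cluster 2 held 473. The 0 calls of cluster 12 by edgeR stood beside 1817 regions at an unadjusted p under 0.05 without intact head replicate 1 and 3142 without intact head replicate 2.

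The effects in clusters 1, 2 and 4 went together, with correlations of log2 fold changes across regions of 0.51 to 0.61 between them, and so did those in clusters 5, 12 and 17, at 0.50 to 0.55. Effects in cluster 11 correlated with those in the other 8 clusters with at least 200 calls at 0.03 to 0.16. These clusters come from the same 4 libraries, which alone gave a covariance of 0.0113 between clusters 1 and 4 against an observed 0.202, and of 0.00334 between clusters 1 and 11 against 0.0105. Clusters 1 and 4 shared 807 regions higher in both, against 145 for independent lists, and 233 lower in both against 34.8. Clusters 1 and 11 shared 106 and 15, against 95.2 and 25.4, and 152 regions were called in opposite directions. Cluster 11 shared 145 higher regions with cluster 12, against 75.6 for independent lists, 142 with cluster 5 against 88.9, 85 with cluster 4 against 50.1, 55 with cluster 17 against 26.2, 34 with cluster 2 against 22.8, 25 with cluster 7 against 7.13 and 14 with cluster 8 against 6.72. In these 7 pairs, 1 to 12 regions were lower in both, against 0.712 to 18.4, and 5 to 131 were called in opposite directions. For opposite calls, here and between clusters 1 and 11, no number for independent lists was worked out. Independent lists would also give some, so these counts alone show no excess.

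**Figure D5:**
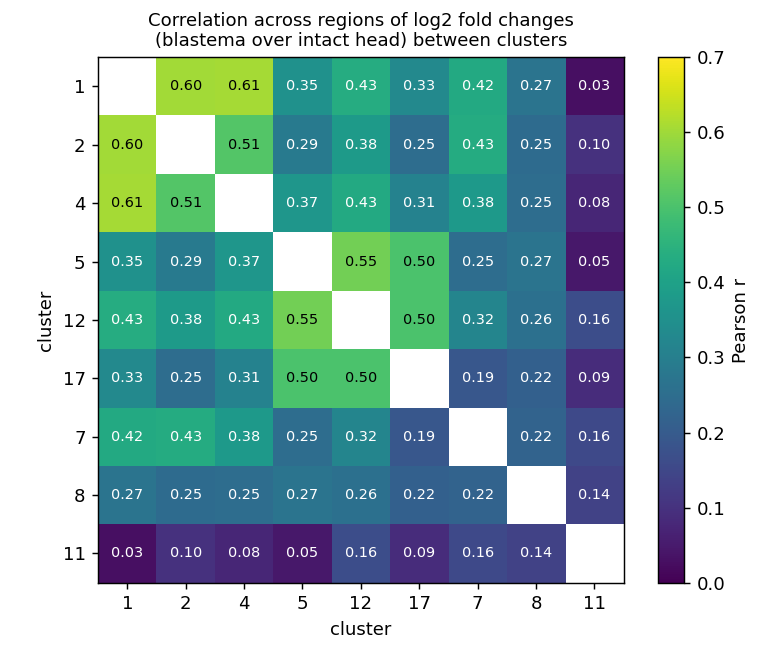
Pearson correlation across regions of the log2 fold change of blastema over intact head between pairs of clusters with at least 200 called regions (both axes, cluster number; colour, r). Cluster 11 has correlations of 0.03 to 0.16 with the others, and clusters 1 and 4 have one of 0.61.

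A direct test of the difference, with the library as a block and clusters 1, 4, 5, 11 and 12 in 1 edgeR fit, called 2889 of 25186 regions. The 3 regions with the smallest adjusted p were picked after their values were seen. Scaffold1183:118190-119137 rose by 1.40 (SE 0.14) in cluster 11 and had log2 fold changes of -0.47 to -0.11 in the other 4 clusters (adjusted p = 1.15e-16, edgeR). Scaffold469:197005-197922 had a log2 fold change of -0.78 (SE 0.15) in cluster 11 and rose by 1.67 (SE 0.12) in cluster 1 and 1.79 (SE 0.15) in cluster 4 (adjusted p = 7.61e-21, edgeR). Scaffold545:158009-158832 rose by 1.64 (SE 0.18) in cluster 1 and 2.05 (SE 0.25) in cluster 4, against 0.03 (SE 0.11) in cluster 11 (adjusted p = 6.79e-21, edgeR).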

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

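In this part, the shares without doublets and among nuclei with at least 2000 fragments were planned, although the bounds they were read by were set after their values had been seen, the test of the finer sub-clusters was set before its result was seen, and the other tests were chosen after the results they bear on had been seen.

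The effect of blastema against intact head differed among clusters 1, 4, 5, 11 and 12 in 2889 of 25186 regions by a direct test of the difference. Against the mean of the other 4 clusters, it differed in 2183 regions in cluster 11, in 694 in cluster 5, in 453 in cluster 1, in 87 in cluster 4 and in 25 in cluster 12. In clusters 1, 5 and 11 the groups held sub-clusters in different shares, as given above, and these counts do not take that into account. In a simulation with the real library sizes this test recovered 27.8% of 4-fold and 0% of 2-fold differences. The simulation changed 200 regions in cluster 1 alone, with an assumed spread. That is far fewer than were called in the data, which makes the adjusted threshold stricter, so these rates are not the recovery in the data.

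Barcodes outside the called nuclei, which no comparison of the report uses, also carried a group difference. They held 5491806, 3758130, 4206431 and 4227747 fragments in the intact head replicates 1 and 2 and the blastema replicates 1 and 2, and 53.1%, 58.6%, 58.1% and 58.6% of these lay in the union regions. An edgeR fit of them called 127 regions, 116 of them called in the same direction in nuclei. Of the 26242 regions called in nuclei, 87.0% had the same sign there. No explanation was tested, and 587, 808, 766 and 615 of these barcodes, in the same order, held at least as many fragments as the lowest 5% of nuclei reached.

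Cluster 11 stood apart from the other 8 clusters with at least 200 calls, with a median correlation of effects of 0.0948 against 0.342 among the others. Few fragments do not account for it, since the other clusters thinned to the fragments of cluster 11 kept a median correlation of 0.359 among themselves, the lowest being 0.187. Nuclei scored as doublets, 9.49% of the cluster, do not account for it either, as the median was 0.0921 without them, although 953 in place of 1447 regions were then called. Doublets that the score missed stay open, since it used an assumed rate. A shift between sub-clusters stays open: in the main sub-cluster alone, with 76 and 97 intact and 349 and 353 blastema nuclei, the median correlation was 0.185, with a range of 0.13 to 0.25, against 0.315 for equal draws of the others. Depth per nucleus also differed, with medians of 4886 and 3138 fragments in intact heads against 2302.5 and 2710 in blastema, and a difference of the tissues remains untested.

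By their median, regions higher in blastema rose by more than the shares of the clusters predict. With cluster profiles from replicates of 1 number and fragment shares from those of the other, the predicted median was at most 35.0% of the observed one for higher regions, against 59.3% and 61.8% for lower regions. With 31 sub-clusters it was at most 40.5% for higher regions, which leaves shifts among states finer than these open. The regions were called with the same 4 libraries, which can raise the observed medians and not the predicted ones. With profiles from all 4 libraries, 862 regions with rises of 0.25 to 0.5 in log2 fold change had a predicted median of 0.38. For 2846 regions with rises of 1 to 1.25 it was 0.26. A difference in how the libraries were made cannot be told apart from the group, because both libraries of a group would share it. Differences between single libraries gave 9.97% of the covariance of the effects between clusters.

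The shares of 13 clusters differed between the groups. Without nuclei scored as doublets, 13 of these 13 differences kept their call and direction. With clusters built without the regions called within any cluster 10 did, while clusters 2 and 12 had merged with others and cluster 3 missed the threshold. The 10 count merged clusters under the numbers 1 and 11, with 6516 and 2659 nuclei against 4084 and 1096 in the main clusters. This setting thus cannot show whether clusters 1, 2, 11 and 12 keep their calls on their own. Regions called only in the whole libraries were not left out for it. Among nuclei with at least 2000 fragments, 9 differences kept their call and direction and cluster 2 could not be matched. Clusters 3, 9 and 21 missed the threshold there, with log2 ratios of -0.67 (SE 0.28), -1.22 (SE 0.44) and -3.08 (SE 1.15). With all nuclei these ratios were -0.80 (SE 0.26), -0.81 (SE 0.26) and -1.92 (SE 0.32). In clusters 9 and 21 the calls thus ended with larger errors and not with smaller differences. Ratios of other called clusters moved among these nuclei too. Their size rose in clusters 1 (0.89 to 1.71) and 12 (0.76 to 1.27) and fell in clusters 11 (1.12 to 0.90) and 19 (-1.76 to -1.28). A part played by shallow nuclei thus stays open for the shares as a whole. Cell loss during preparation was not tested, and a difference of the tissues stays among the open explanations.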

How the results depend on the processing

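The leaving out of doublets in the tests of regions, the thinning to equal depth, the clusters with at least 200 nuclei, the clusters without changed regions and the ranking of clusters in 1 group were chosen after seeing the data. The count of 26242 regions lay between 23229 and 27738 under 9 other settings. It was 8276 with the DESeq2 Wald test, 8275 of these shared with edgeR, and 16377 with fragments under 120 bp, with 74221 regions tested. Leaving out 1 library gave 11838 to 25994, with fewer samples. Of regions called, 54.2% were higher, against 48.5% with all fragments as library size and 45% with short fragments. Of 264 values of the 24 named regions under other settings, 263 kept direction and call and 1 missed the threshold, and all 96 values with 1 library left out kept both. Of 336 values of the regions named within clusters under other settings, 310 kept both and 26 missed the threshold, as did 74 of 340 with 1 library left out. Within clusters, 13246 calls became 7589 with equal nuclei and 4242 to 11836 with 1 library left out. The cause was not tested beyond the fewer nuclei and samples. The 13 called shares became 8 to 12 with 1 library left out and 11 to 14 otherwise. No called share and no named region, in the whole libraries or within clusters, changed sign where it was tested, while 3 log2 ratios of shares that were not called did: clusters 4 (-0.35) and 5 (0.32) among nuclei with at least 2000 fragments and cluster 7 (-0.22) with components centred per library. With short fragments, 57 of the regions called had the opposite sign. Mean peak overlap was 75%, 74.3% with at least 50% of the shorter peak and 79.2% for the upper 50% of lists. With a replicate block, 27738 regions, 12535 within clusters and 13 shares were called, with 841 in place of 1584 in cluster 4, 88 for 245 in cluster 7, 2 for 16 in cluster 6, 229 for 118 in cluster 10, 201 for 50 in cluster 13, 5 for 1 in cluster 16, 23 for 0 in cluster 3 and 2 for 0 in cluster 18. Cluster 20 then held 0 calls by edgeR in place of 16, with 284 regions at an unadjusted p under 0.05, and cluster 15 again missed the threshold for shares (adjusted p = 0.192, edgeR). Deviations of same-numbered libraries correlated at 0.0055 across regions, so no shared deviation was seen. This cannot show whether libraries of 1 number were prepared as a pair. The other 2 splits of the 4 libraries called 0 regions by edgeR, with 478 and 439 at an unadjusted p under 0.05. Each of them put an intact and a blastema library on both sides, so the group difference entered the spread within a side. Few calls were thus likely in any case, and the 0 does not bear on the group calls. 3 splits are too few to set a chance level. At this depth and number of libraries, 57% of 2-fold changes were recovered in simulated whole libraries. The simulation changed 200 regions, far fewer than were called in the data, so this is not the recovery in the data. Genes, gene lists, motifs and GC correction were not run.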

Other observations

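The tests in this part were all chosen after the values had been seen.

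Regions called in several clusters in 1 direction were not always called in that direction in the whole libraries. Of 778 such regions in at least 3 clusters, 672 higher and 106 lower in blastema, 617 were called in that direction in the whole libraries, 156 were not called there and 5 were called in the opposite direction. Scaffold866:56086-57031 was higher in blastema in clusters 1, 2, 4, 5 and 17, with a median log2 fold change of 1.19, yet had a log2 fold change of -0.55 (SE 0.11) in the whole libraries (adjusted p = 9.14e-05, edgeR). Scaffold233:759581-760508 was higher in clusters 5, 12 and 17, with a median of 1.20, and had one of -0.76 (SE 0.11) in the whole libraries (adjusted p = 6.75e-08, edgeR). Scaffold369:613384-614373 was higher in clusters 1, 2 and 4, with a median of 2.33, against -0.42 (SE 0.14) (adjusted p = 0.0231, edgeR). Scaffold273:485340-486301 was higher in 7 clusters, with a median of 0.94, and had a log2 fold change of -0.09 (SE 0.10) in the whole libraries (adjusted p = 0.578, edgeR).

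Called regions lay next to each other on scaffolds. Neighbouring tested regions were both higher or both lower in 4906 pairs, against a mean of 2695 and a highest value of 2846 in 1000 shuffles of the calls over regions (permutation p = 0.001, the smallest they can give). Pairs of opposite direction numbered 1643, against a mean of 2659. There were 72 runs of at least 5 neighbours in 1 direction, 54 higher and 18 lower, against a mean of 2.72 in 100 shuffles. The longest held 10 regions higher in blastema over 40.8 kb at scaffold336:76390-117199, with log2 fold changes of 0.48 to 1.51. At scaffold267:29579-49088, 9 regions were lower, with a median of -1.01. At scaffold216:491267-717498, 7 regions over 226.2 kb were higher, with a median of 1.52. Shuffling ignores that neighbours may be open in the same clusters, and that a fragment with its ends in 2 regions counted in both.

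Among regions at or above the median coverage, the called ones (8643 higher and 9615 lower) were open in fewer clusters than lists of like coverage. These lists were drawn from all such regions, called ones included. The effective number of clusters had a median of 13.5 for higher and 12.3 for lower regions, against 15.2 and 15.1 in 1000 matched lists (permutation p = 0.001, the smallest they can give). A shift in cluster shares changes the whole-library counts only of regions unequally open over clusters. Fewer clusters were thus likely for called regions from the shares alone, and this p-value does not go beyond that. Clusters were then ranked for each region by the mean CPM of the 4 libraries with equal weight. Of the regions at that coverage most open in cluster 11, 50.7% were higher in blastema, followed by 40.7% in cluster 1 and 39.8% in cluster 2. Of the regions most open in cluster 16, 45.3% were lower, followed by 42.9% in cluster 9 and 40.6% in cluster 14. This order depended in part on the libraries used to rank clusters. In intact heads alone, the shares higher were 40.9% in cluster 11, 36.7% in cluster 4 and 34.1% in cluster 1, and the shares lower were 47.6% in cluster 16, 45.1% in cluster 9 and 42.6% in cluster 14. In blastema alone, they were 55.3% in cluster 11, 51.8% in cluster 1 and 45.3% in cluster 2, and 41.3% in cluster 16, 40.9% in cluster 14 and 36.8% in cluster 9. The first cluster by all libraries was also the first by intact heads alone in 71.9% of higher and 72.9% of lower regions. These calls come from whole libraries, where a shift in the share of a cluster alone moves the regions most open in it. Clusters 11, 1 and 2 held larger shares of blastema nuclei and clusters 16, 9 and 14 smaller ones, as given above. The order of clusters thus cannot be told apart from the shift in shares. Over all 62974 regions at or above the median coverage, 8643 were higher and 9615 lower. In cluster 15, 11% were higher and 15.2% lower. In cluster 21, with 240 nuclei, 6.56% were higher and 5.05% lower.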
